A study of Haliotis discus hannai with 24 samples.

How the data were processed

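Polyadenylated RNA of left and right eyestalks, cephalic tentacles and epipodial tentacles of Haliotis discus hannai was sequenced, with 4 libraries per organ and side. Total RNA was taken with TRIzol and libraries were made with the VAHTS Universal V6 kit, per the labels' protocols. All libraries carry the same batch value, per the labels. The submitters' processing notes name fastp, HISAT2 and HTSeq, without versions. The genome build, the annotation and the strand setting are not given in the sources used here. Overlapping genes, and near-identical gene copies, are therefore uncertain.

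The deposited tables give 1 whole-number read count and 1 FPKM value per gene and library for 19700 genes. The read counts are deposited as raw values per gene with no normalization, which the values show: they are whole numbers with a different total in each library. The deposited FPKM values equal the count over the coding length and the library's total count, in the usual units, with relative deviations below 1e-07. A length recovered from this relation was whole within 0.001 for 100% of the 17233 genes with a count, and 99.4% of these lengths were divisible by 3, with a median coding length of 603. The FPKM values thus carry the same information as the counts, without a composition factor, and 0 cells differed in being 0 or not. No entry names anything other than a gene, and every column belonged to a labelled library.

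Groups were taken from the tissue labels and replicate numbers from the titles. The side of the epipodial libraries follows the tissue label, with which the letter of the title and, for the libraries labelled left, the treatment label are in conflict. No libraries held identical values: the chi-square per gene was 30.5 at the least between libraries of 1 group and 4.69 at the least between left and right libraries of 1 number, in the epipodial tentacle.

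Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr over the 6 groups, which left 7341, and scaled with TMM factors. A quasi-likelihood model with 6 group means was fitted to all 24 libraries with robust dispersion, leaving 18 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The contrasts were left against right in each organ, their average over the eyestalk and the cephalic tentacle, the 3 differences of the left-right effect between organs, and the 3 pairs of organs. Log2 fold changes are left over right, or the first named organ over the other. Levels are given as CPM scaled with the TMM factors. Folds against organs with 0 counts were computed from pooled counts against a floor of 3 counts over the group, and those with 1 to 3 counts as pooled ratios with exact Poisson intervals at the 95% level. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

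The tests, the contrasts, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, among called genes whose 2 groups did not overlap in log2 CPM and which carry an informative name, the 10 with the largest fold change in each direction. It also took up to 4 called members of each gene list, the kinase subunit, CREB-binding protein and Smad genes of the left-right contrasts, and the Pitx and Nodal genes. The files pair 0 identifiers with names, so the condition on the name was dropped and at most 2 genes per direction are given. The 29 gene lists that had been fixed, among them those for cAMP-PKA-CBP and TGF-β signalling and the cell type markers, could not be matched to identifiers, and no list was tested. Genes and alternatives chosen after their values were seen are said to be so.

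Pairing by replicate number was checked by the correlation across genes of the libraries' deviations from their group means, with a bound of 0.1 for every number. Left and right epipodial libraries passed (0.77, 0.74, 0.68 and 0.77), with an exact permutation p of 0.0417 over 24 assignments, the smallest these can give (adjusted p = 0.05 over the 6 checks). The averages of both sides passed between the eyestalk and the cephalic tentacle (0.21 to 0.45), the eyestalk and the epipodial tentacle (0.36 to 0.56) and the tentacles (0.36 to 0.55), each with the same exact p of 0.0417. Left and right eyestalks did not pass the bound, since the correlation in number 1 was -0.13, although their exact p was also 0.0417, and left and right cephalic tentacles did not pass it either (exact p = 0.5). Whether a number stands for an animal is not given in the sources used here.

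The test was run on simulated counts with the real library sizes and 200 genes changed by known folds. Each gene otherwise had the same mean and spread in every organ, so levels and spread that differ between organs were not reproduced. For the organ comparisons the test recovered 12% to 16% of genes changed 4-fold and 46% to 62% of those changed 8-fold. Of those changed 16-fold it recovered 70% to 76%. Detection was compared at equal depth by thinning each library to 470000 counts, and to 330000 counts after removing its 10 most abundant genes.

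The alternatives fixed beforehand were RLE factors, library totals without a factor, no filter, a stricter filter of 10 counts in 8 libraries, a fit without robust dispersion, DESeq2 1.42.0, limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1) with and without a minimum of 0.5 FPKM in 4 libraries, fits of only the groups compared, the replicate number as a block, a minimum log2 fold change of 1, and each library left out in turn. Fits without the 8 doubted libraries, limma with voom sample weights and a paired fit of the epipodial libraries were added after the data were seen. A library was doubted when it had fewer than 6000 genes detected or a single gene above 50% of its counts. Total counts ranged from 473072 to 4479096. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the library measures and figures.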

Results

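Messenger RNA was profiled in 3 kinds of sensory organ of the Pacific abalone Haliotis discus hannai, a marine snail: the eyestalk, the cephalic tentacle of the head and the epipodial tentacle that fringes the foot. Each organ was taken from the left and from the right side, with 4 libraries in each of the 6 groups and 24 in all. Nothing in the sources used here says how many animals stood behind the libraries, so p-values measure the spread between these libraries. The organ comparisons count the left and the right library of a number as separate units. If both came from 1 animal, the p-values and standard errors of these comparisons would not measure the spread between animals. Of 19700 genes listed, 17233 had at least 1 count and 7341 entered the tests. The files do not pair the gene identifiers with names, so genes are given by identifier and at most 2 in each direction are named per comparison.

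The total count was 1692939 to 4479096 in the right eyestalk, 1737333 to 2201621 in the left eyestalk, 473072 to 1872059 in the right cephalic tentacle and 494495 to 1939936 in the left cephalic tentacle. It was 1700095 to 1981178 in the epipodial libraries labelled right and 1782220 to 2146464 in those labelled left. The epipodial libraries had 8876 to 10678 genes with a count, the eyestalk libraries 3682 to 11090 and the cephalic libraries 3919 to 11197. Fewer than 6000 genes were detected in 7 libraries: 3 of the 8 eyestalk libraries, 4 of the 8 cephalic libraries and 0 of the 8 epipodial libraries. In right eyestalk replicate 2 a single gene, HDSC05049CG00020, held 70.8% of the counts, and in right eyestalk replicate 1 it held 24.1%. These 8 libraries were kept in the tests, and the counts of called genes and the organ sets are also given without them.

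**Figure D1:**
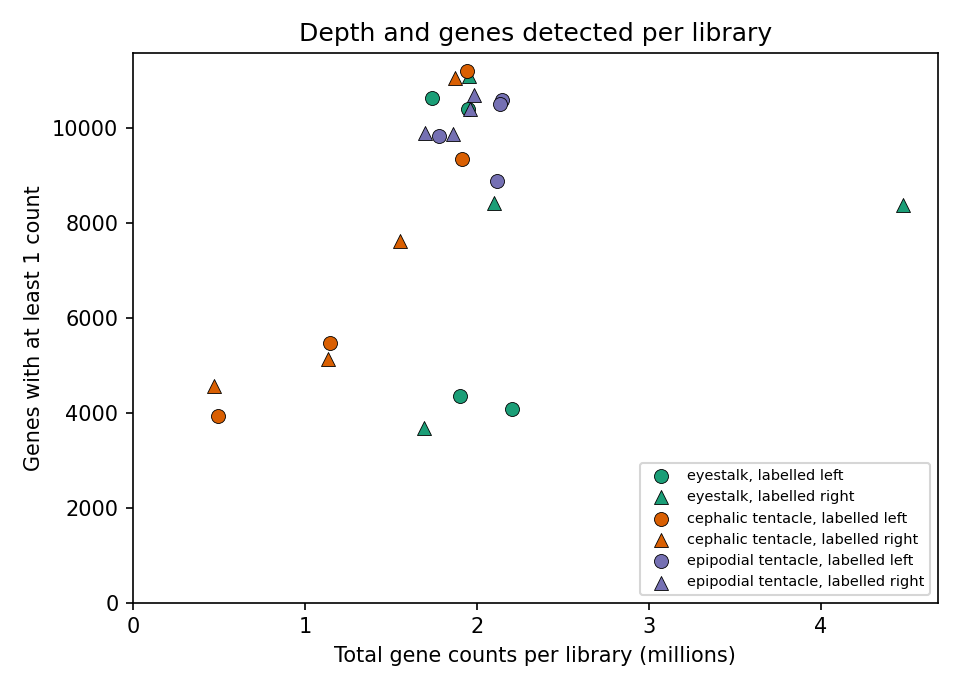
Genes with at least 1 count in each library (vertical axis) against its total gene count (horizontal axis), with colour for the organ and shape for the labelled side. The 7 points under 6000 genes are eyestalk and cephalic libraries, and the 3 eyestalk points among them have totals similar to those of most other libraries.

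The labels of the epipodial tentacle were in conflict. The titles of the libraries labelled left begin with the letter that marks the right side in the other organs, and the reverse holds for those labelled right. The treatment label of the libraries labelled left also names the cephalic tentacle. The epipodial libraries are therefore described by the side their tissue label gives, and any direction drawn from it depends on that label.

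The design asks first how the left and the right organ of a kind differ. In the eyestalk no gene reached an adjusted p under 0.05, and the 2 named genes that were highest against the tentacles spanned overlapping ranges on both sides. The gene HDSC06460CG00010 ranged from 4056 to 173260 CPM (counts relative to the library total times its TMM factor, so not a share of the library) in the 4 left eyestalk libraries and from 752 to 375417 CPM in the 4 right ones. HDSC04127CG00020 ranged from 482 to 16389 CPM on the left and from 117 to 57233 CPM on the right. edgeR's quasi-likelihood test called 0 of 7341 genes after Benjamini-Hochberg adjustment, with 180 genes (2.45%) at an unadjusted p under 0.05. DESeq2, limma on the FPKM values and limma with voom weights each called 0 genes. Without the 8 doubted libraries edgeR called 0 genes in each left-right contrast and each difference of them, with 109, 360 and 22 genes at an unadjusted p under 0.05 in the eyestalk, cephalic and epipodial tentacle. This fit tested 8333 genes. It had only 2 libraries per side in the eyestalk and the cephalic tentacle, against 4 per side in the epipodial tentacle, so its 0 calls are a weak check. Differences of moderate size were not recovered in simulated data with these library sizes: 0 of 50 genes changed 8-fold were recovered and 5 of 50 changed 16-fold. The simulation gave a gene the same mean and spread in every organ, so this recovery need not hold for the eyestalk's own levels and spread. The 95% interval of the left-right fold excluded a 4-fold difference for 1087 genes, 14.8% of those tested.

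In the cephalic tentacle edgeR called 0 genes between the sides, with 100 (1.36%) at an unadjusted p under 0.05, and DESeq2, limma on FPKM and limma with voom weights each called 0. With no filter on low counts edgeR called 1 gene, HDSC01355CG00060, which was singled out after its values were seen, with a log2 fold change of -7.65 (adjusted p = 0.0355). In simulated data 6 of 50 genes changed 8-fold and 13 of 50 changed 16-fold were recovered. The interval excluded a 4-fold difference for 985 genes (13.4%). Averaged over the eyestalk and the cephalic tentacle, the left-right contrast had 0 calls and 116 genes at an unadjusted p under 0.05, and the interval excluded a 4-fold difference for 2797 genes (38.1%). Here too DESeq2, limma on FPKM and limma with voom weights called 0 genes.

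In the epipodial tentacle the median absolute log2 fold change between sides was 0.26, against 0.53 in the eyestalk and 0.60 in the cephalic tentacle. Without the 8 doubted libraries it was 0.28, 0.49 and 0.77 over 8333 genes. That fit had 4 libraries per side in the epipodial tentacle but 2 per side in the eyestalk and the cephalic tentacle, so these sizes are not on equal terms. These sizes also carry the noise between libraries, and the common biological coefficient of variation was 0.607 in the epipodial tentacle, 1.08 in the eyestalk and 0.988 in the cephalic tentacle. With the replicate number as a block it was 0.233, 1.04 and 1.02. edgeR called 0 genes in the fit of all 24 libraries, with 4 (0.0545%) at an unadjusted p under 0.05, far fewer than chance alone would give. The 180 in the eyestalk and the 100 in the cephalic tentacle were also fewer. This fit shares its spread between organs and leaves out the pairing by number. In the epipodial tentacle, with its lower spread and its pairing by number, the left-right test therefore looks too cautious. In the eyestalk and the cephalic tentacle the spread was higher and moved little with the block. Sharing the spread and leaving out the pairing therefore do not account for their low counts, the cause of which was not tested. In each organ 0 calls from this fit say little. DESeq2 called 1 gene, HDSC01242CG00030, and limma on log2(FPKM + 0.1) called 1, HDSC69893CG00010, while limma on log2(FPKM + 1) and limma with voom weights called 0. Both genes were lower in the libraries labelled left and were singled out after their values were seen.

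Left and right epipodial libraries with the same replicate number deviated together from their group means, with correlations across genes of 0.77, 0.74, 0.68 and 0.77 in the 4 numbers. A fit of the 8 epipodial libraries alone, paired by number and chosen after the data were seen, tested 5740 genes and called 1 of them, HDSC01860CG00060. In this paired edgeR fit that gene was higher in the library labelled left in 4 of 4 pairs, with a log2 fold change of 2.33 (SE 0.38, adjusted p = 0.0399). Its counts were 436 against 53 in number 4 but 14 against 12 in number 3. In the fit of all 24 libraries the log2 fold change of HDSC01860CG00060 was 2.80 and it was not called. The paired fit had 435 genes at an unadjusted p under 0.05, where 287 are due by chance. Its intervals excluded a 2-fold difference between sides for 3379 genes (58.9%) and a 4-fold difference for 5556 genes (96.8%). In 1 simulated set the paired fit recovered 6 of 50 genes changed 1.5-fold, 31 of 50 changed 2-fold and 50 of 50 changed 4-fold or 8-fold. Beside these it made 14 false calls, a larger share of its calls than the threshold of 0.05 stands for. A single call by this fit is therefore weak.

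**Figure D2:**
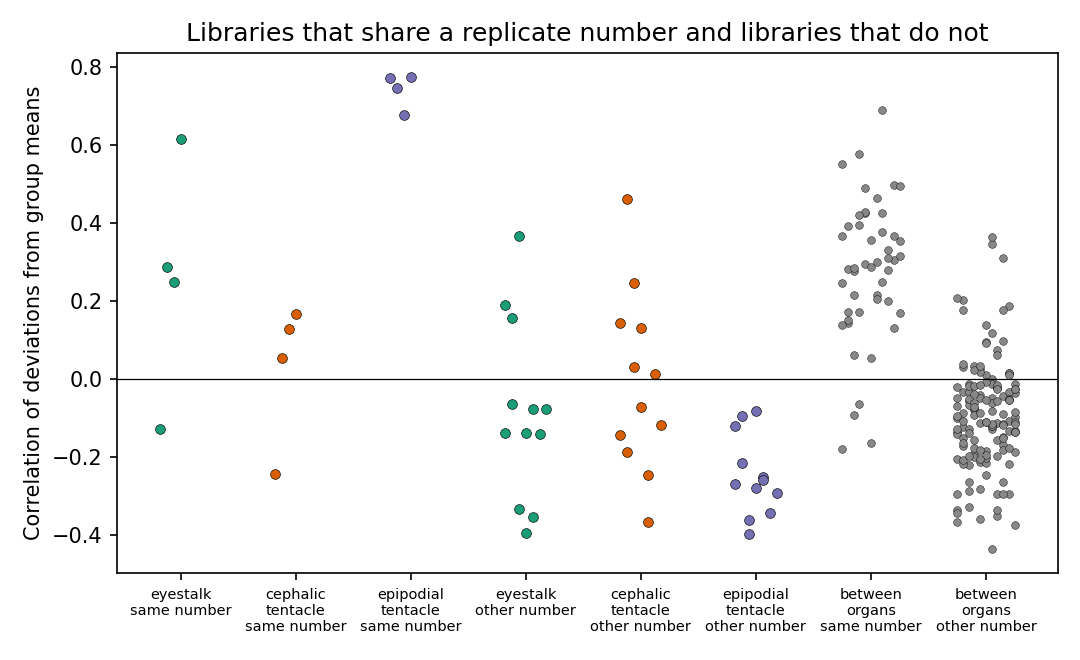
Correlation across genes of 2 libraries' deviations from their group means, for left and right libraries of 1 organ and for libraries of different organs, with the same or another replicate number. The 4 epipodial pairs of the same number lie between 0.68 and 0.77. Deviations are centred on groups of 4, which draws pairs of another number below 0 when those of the same number lie above it.

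The left-right effect itself was compared between organs. Between the eyestalk and the cephalic tentacle edgeR called 0 genes, with 181 at an unadjusted p under 0.05. Between the cephalic and the epipodial tentacle it called 0, with 50 at an unadjusted p under 0.05, and DESeq2 called 1, HDSC01242CG00030, singled out after its value was seen. Between the eyestalk and the epipodial tentacle it called 0, with 64 at an unadjusted p under 0.05. DESeq2 called 0 genes in the first and the last of these contrasts, and limma called 0 in all 3.

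**Figure D3:**
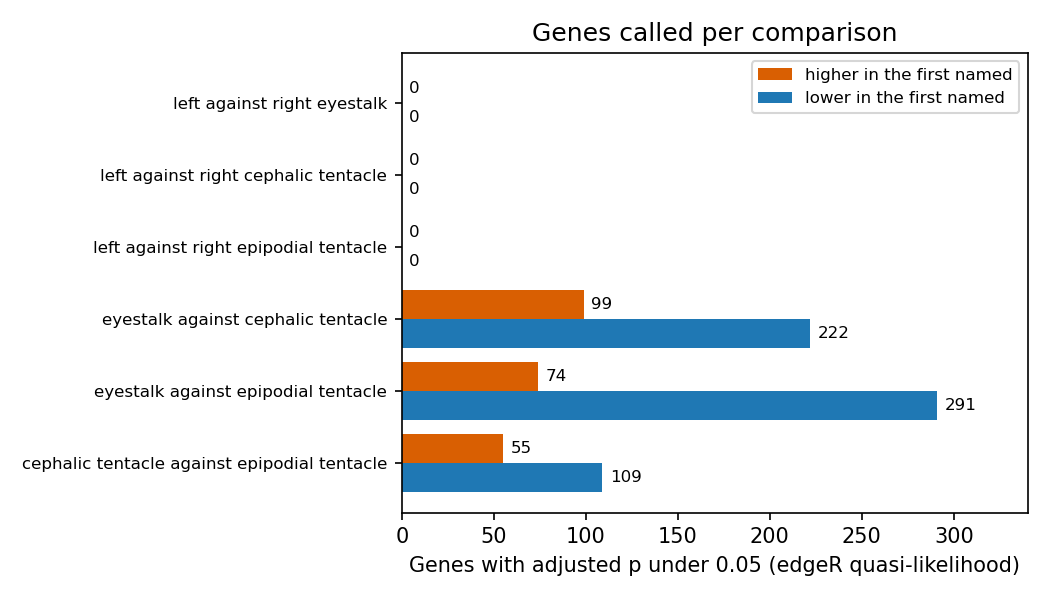
Number of genes with an adjusted p under 0.05 in edgeR's quasi-likelihood test for the 3 left-right and the 3 organ comparisons, with bars for genes higher and lower in the first named group. The left-right bars are all 0, and the organ bars range from 55 to 291 genes.

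The organs differed from each other. Against the cephalic tentacle the eyestalk had 99 genes higher and 222 lower. With RLE factors these were 107 and 168, and with library totals alone 63 and 166. The genes with the most extreme rise were at very high levels in the eyestalk and nearly or wholly without counts in the tentacles. HDSC06460CG00010 averaged 100795 CPM in the eyestalk ± 132315 (SD, n = 8), with 881253 counts there and 2 counts in the cephalic tentacle, a pooled ratio of 340060 with a 95% counting interval of 94138 to 2807990 (edgeR adjusted p = 1.9e-05). HDSC04127CG00020 averaged 11855 CPM ± 19631 (SD, n = 8) in the eyestalk and had 0 counts in all 8 cephalic libraries, at least 30660-fold higher against a floor of 3 counts over the group, or at least 12591-fold without right eyestalk replicate 2 (edgeR adjusted p = 0.0174). Of the genes lower in the eyestalk, HDSC67339CG00010 averaged 0.369 CPM ± 0.611 (SD, n = 8) there and 136 CPM ± 249 (SD, n = 8) in the cephalic tentacle, a log2 fold change of -8.02 (SE 1.06). HDSC00448CG00040 averaged 1.90 CPM ± 3.27 in the eyestalk and 304 CPM ± 247 in the cephalic tentacle, a log2 fold change of -7.73 (SE 0.83). In the 3 eyestalk libraries of low detection and the 1 with a dominating gene, HDSC06460CG00010 was at 82295 to 375417 CPM and HDSC04127CG00020 at 2450 to 57233 CPM, and in the other 4 they were at 752 to 6690 and 117 to 1492 CPM. Single libraries carried some of these means. Without right eyestalk replicate 1 HDSC06460CG00010 averaged 61564 CPM in the eyestalk, and without right eyestalk replicate 2 HDSC04127CG00020 averaged 5372 CPM. HDSC67339CG00010 was at 746 CPM in left cephalic tentacle replicate 4 and at 11.6 to 93.5 CPM in the other 7 cephalic libraries, and without that library they averaged 48.4 CPM and the log2 fold change was -6.37. The low eyestalk means fell to 0.177 CPM for HDSC67339CG00010 without right eyestalk replicate 3 and to 0.788 CPM for HDSC00448CG00040 without right eyestalk replicate 4. The ranges of the 4 genes named here did not overlap between the organs, so each was higher or lower in 8 of 8 libraries against 8. The rule for named genes requires this, so it is no added support.

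In this comparison 20 of the genes called higher and 40 of those called lower had no overlap between the 8 and the 8 libraries. If the 16 libraries were independent, chance would give 0.0155% of genes, or 1.14 of 7341. Libraries of 1 number may come from 1 animal, and chance would then give more, so the excess over chance is not known. Without the 8 libraries of low detection or a dominating gene, edgeR called 362 genes, 125 higher and 237 lower, of which 201 were among the 321. A fit of only the 16 eyestalk and cephalic libraries called 177 genes.

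Against the epipodial tentacle the eyestalk had 74 genes higher and 291 lower. HDSC06460CG00010 and HDSC04127CG00020 again had the most extreme rise. The 8 epipodial libraries held 2 counts of HDSC06460CG00010, a pooled ratio of 560512 with a counting interval of 155165 to 4628330 (edgeR adjusted p = 1.1e-05). They held 0 counts of HDSC04127CG00020, at least 50537-fold lower than the eyestalk, or at least 20754-fold without right eyestalk replicate 2 (edgeR adjusted p = 0.0136). HDSC01786CG00010 and HDSC00168CG00070 had 0 counts in all 8 eyestalk libraries and averaged 61.2 CPM ± 26.6 and 56.6 CPM ± 14.7 (SD, n = 8) in the epipodial tentacle. They were at least 328-fold and 292-fold lower in the eyestalk, each in 8 of 8 libraries, as the rule for named genes requires.

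Of the called genes, 21 higher and 137 lower had no overlap between the libraries of these 2 organs. The higher genes were 20.3% of the calls with TMM factors, 30.1% with RLE factors and 8.31% with library totals alone. The median log2 fold change of all tested genes moved with the scaling: it was -0.18 with TMM, 0.01 with RLE and -0.44 with library totals. Without the 8 doubted libraries edgeR called 455 genes, 146 higher and 309 lower, of which 238 were among the 365. DESeq2 called 568 genes, 210 higher and 358 lower.

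**Figure D4:**
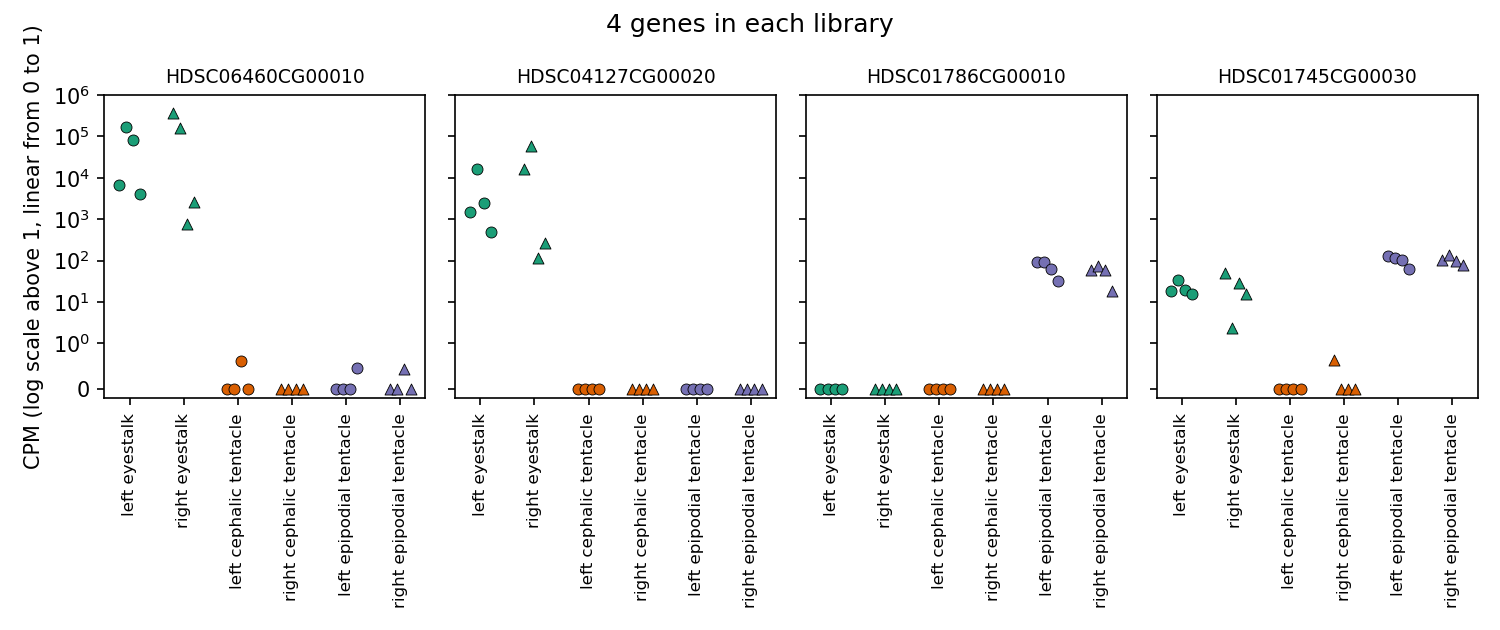
CPM of 4 named genes in each of the 24 libraries, on an axis that is logarithmic above 1 and linear from 0 to 1, by organ and labelled side. HDSC06460CG00010 and HDSC04127CG00020 lie above 100 CPM in all eyestalk libraries and below 1 CPM in all tentacle libraries, while HDSC01786CG00010 has counts in the epipodial libraries alone and HDSC01745CG00030 in the eyestalk and epipodial libraries and 1 cephalic library.

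Between the tentacles, the cephalic tentacle had 55 genes higher and 109 lower than the epipodial tentacle. With RLE factors these were 56 and 108, and with library totals alone 27 and 87. HDSC01199CG00030 averaged 35.2 CPM ± 32.0 in the cephalic and 0.240 CPM ± 0.444 in the epipodial tentacle (SD, n = 8 each), a log2 fold change of 7.53 (SE 1.27, edgeR adjusted p = 0.000627). HDSC01568CG00090 averaged 49.8 CPM ± 85.7 and 0.607 CPM ± 0.732, a log2 fold change of 6.01 (SE 1.09, edgeR adjusted p = 0.00122). Left cephalic tentacle replicate 4 was at 260 CPM of HDSC01568CG00090, and without it the other 7 averaged 19.7 CPM, with a log2 fold change of 4.82 (edgeR adjusted p = 0.0213). The epipodial mean of HDSC01199CG00030 fell to 0.135 CPM without left epipodial tentacle replicate 1 and to 0.139 CPM without replicate 4. HDSC01786CG00010 had 0 counts in the 8 cephalic libraries, as in the eyestalk, and was at least 253-fold lower there than in the epipodial tentacle. HDSC01745CG00030 had 2 counts in the cephalic tentacle against 2072 in the epipodial tentacle, where its 8 libraries ranged from 63.2 to 137 CPM. The ratio of epipodial to cephalic was 629, with a counting interval of 174 to 5193.

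In this comparison 9 genes called higher and 80 called lower had no overlap. Libraries with the same number deviated together across these organs, and with the replicate number as a block edgeR called 254 genes, 88 higher and 166 lower, which included 163 of the 164. Without the 8 doubted libraries it called 206 genes, 80 of them higher, with 104 shared. DESeq2 called 310 genes.

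The comparisons were then joined to find genes that set 1 organ apart from both others. The eyestalk had 35 genes higher than in both tentacles and 127 genes lower than in both. The cephalic tentacle had 24 genes higher and 33 lower than in both other organs, and the epipodial tentacle 51 higher and 15 lower. In the epipodial set of 51 higher genes, 9 were at or under 3 counts over each of the other organs, and 28 had no overlap with any library of the other organs. In the eyestalk set of 35 higher genes, 4 were at or under 3 counts over each tentacle and 11 had no overlap. In the cephalic set of 24 higher genes, 0 were at or under 3 counts over each other organ and 1 had no overlap. Without the 8 doubted libraries the sets of higher genes held 45, 42 and 46 genes in the eyestalk, cephalic and epipodial tentacle, with 19, 15 and 30 shared, and the sets of lower genes 134, 51 and 15, with 73, 22 and 4 shared. Independent lists of the same sizes would share 1.00 and 8.80 genes for the eyestalk sets, 1.66 and 1.47 for the cephalic sets, and 4.32 and 0.55 for the epipodial sets. With no effect simulated, 10 simulations shared 0 genes in each set, a value of little weight since such data give few calls at all. Each pair of comparisons uses the libraries of 1 organ in common. When these were split between the comparisons, 1 comparison used only left libraries of its organs and the other only right ones. The eyestalk sets then held 6 and 3 genes in 1 split and 6 and 7 in the other. The epipodial sets held 5 and 0 or 8 and 2, and the cephalic sets 1 and 4 or 0 and 6. In the first split, independent lists of these shorter lengths would share 0.049 and 0.133 genes for the eyestalk sets. They would share 0.0306 and 0.0038 for the epipodial and 0.0191 and 0.0294 for the cephalic sets. Left and right libraries of 1 number may come from 1 animal, so the split comparisons need not be independent.

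The 35 genes higher in the eyestalk made up 14.6% to 77.9% of the counts in the 4 doubted eyestalk libraries and 1.68% to 3.62% in the other 4. Their median share was 0.0655% in the cephalic and 0.160% in the epipodial libraries. HDSC05049CG00020, singled out after its values were seen, held 3946374 counts in the eyestalk, 3170629 of them in right eyestalk replicate 2 and 775745 in the other 7 libraries. It held 848 in the cephalic tentacle and 322 in the epipodial tentacle (edgeR adjusted p = 0.000803 and 0.000682 for the eyestalk against each). The 127 genes lower in the eyestalk made up a median of 0.454% of its counts, 4.23% in the cephalic and 3.90% in the epipodial libraries. The 51 genes higher in the epipodial tentacle made up a median of 1.61% of its counts, 0.157% in the cephalic tentacle and 0.0802% in the eyestalk. The 24 genes higher in the cephalic tentacle made up 1.81% of its counts, 0.507% in the epipodial tentacle and 0.183% in the eyestalk.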

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

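All tests of the 3 patterns below were run on the data in which the patterns were seen. Those of sequencing depth, of organ, of organ-specific tissue, of low detection shared within a number, and both tests of the direction of the eyestalk calls were chosen only after the result was seen. The bound for organ-specific tissue was also changed after its values were seen: a first bound, medians below 0 in every pick, would have spoken against more such tissue, but random matched genes had medians of -1.23 and -0.76 too, so the explanation is left open.

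In 7 libraries, 3 of the eyestalk and 4 of the cephalic tentacle, fewer than 6000 genes had a count. Neither depth nor a few abundant genes accounts for this: thinned to 470000 counts the 7 had a median of 4015 genes while the other 17 had at least 5175, and without their 10 top genes the median was 4085 against at least 5968. Loss of transcripts from few starting molecules stays open, since genes at 50 CPM or more in every well-detected library of the organ were at 0 in 0.126% to 5.15% of cases in the 7. The 7 were not alike. Of the genes with a count, 74.8% to 83.5% had at least 10 counts in the 3 eyestalk libraries and 74.0% in left cephalic tentacle replicate 2. The remaining cephalic ones of the 7 had 45.8% to 48.1%, and the other 17 libraries 47.1% to 60.7%. The cause of this was not tested, and the 7 need not share 1 cause. A different cell content stays open too: the same genes were at 0 in pairs of these libraries with a median common odds ratio of 3.89, few genes being at 0. Genes higher in the organ had median log2 differences below 0 in all 6 picks of each organ. These were -2.14 to -0.67 in the eyestalk (median -1.66) and -1.63 to -0.10 in the cephalic tentacle (median -1.30). Random matched genes were below 0 in the median too. The percentiles among them were 0.4 to 72 and 0 to 99.7, so no direction is settled. The 35 genes higher in the eyestalk had a median log2 CPM of 5.17 to 6.71 in its low-detection libraries and 4.82 to 5.09 in its 4 undoubted ones. They were called with these libraries among others, so part of this may come from the picking. The uneven spread over organs, 3, 4 and 0 of 8, had an exact Fisher p of 0.13, so a dependence on the organ may or may not exist.

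Libraries that shared a replicate number resembled each other between left and right epipodial tentacles and between organs averaged over sides, but not between left and right cephalic tentacles (mean correlation 0.027), and left and right eyestalks of number 1 were at -0.13. Low detection shared by a number does not account for it in the epipodial tentacle, which had 0 such libraries and a smallest correlation of 0.68. For the resemblance between the eyestalk and the cephalic tentacle, which both had such libraries, this explanation stays open. Over the 16 libraries without low detection or a dominating gene, 11 genes were at 0 in every library of 1 number and at 10 CPM or more in all others, against at most 7 in 1000 shuffles of the numbers within groups (permutation p = 0.001, the smallest these can give). A candidate explanation is that a number stands for 1 animal or 1 handling day, and the test does not tell these apart. The numbers 1, 2, 3 and 4 had 4, 2, 0 and 5 of these genes.

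In the eyestalk against the epipodial tentacle 291 of 365 calls were lower in the eyestalk. Whether libraries of low detection or with a dominating gene are the cause stays open: without the 8 of them 67.9% of 455 calls were lower, but leaving out 1 more library in turn gave 55.0% to 70.7%, and the jackknife standard error over libraries was 16.3 percentage points. The lower calls outnumbered the higher ones under each scaling, with 79.7% for TMM, 69.9% for RLE and 91.7% for library totals. Their share moved with the scaling, and all these fits held the doubted libraries. The test therefore cannot exclude that scaling plays a part. A difference between the organs themselves, which the design names, remains open and was not tested further.

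A library stood apart from the other 3 of its group in 7 of 50 groups of values looked at, by Dixon's ratio of the gap to the range at its 95% critical value. Chance gives about 1 in 20 for independent, normally spread values. These groups share libraries and genes, and the ratio is 1 by construction where the other 3 libraries are at 0 counts. The 7 of 50 can therefore not be set against that rate. Left epipodial tentacle replicate 4 had 1782220 counts against 2116158 to 2146464 in the other libraries labelled so, a ratio of 0.917. Right eyestalk replicate 2 had 4479096 counts against 1692939 to 2102017, a ratio of 0.853. The gene HDSC00448CG00040 was at a log2 CPM of 3.24 in right epipodial tentacle replicate 2 against 3.88 to 4.00 (ratio 0.839), and in the left eyestalk replicate 4 alone had counts of it (ratio 1). HDSC01786CG00010 was at 4.28 in right epipodial tentacle replicate 4 against 5.88 to 6.19 (ratio 0.839). In the right eyestalk replicate 4 alone had counts of HDSC01199CG00030 (ratio 1). HDSC01568CG00090 was at 8.03 in left cephalic tentacle replicate 4 against 3.96 to 4.45 (ratio 0.879).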

How the results depend on the processing

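Fits without the 8 doubted libraries, with voom weights and of the epipodial libraries alone were chosen only after the data were seen. Of 93 alternative counts for the organ comparisons 77 stayed within 1.5 times the reported count and 16 did not. Of the 45 of these that did not leave out 1 library, 29 stayed within it. Of 201 for the left-right contrasts and their differences 192 were 0, as reported, which shows no stability at the recovery given below. The named genes kept their direction and stayed past the threshold in 358 of 358 alternatives that tested them. They had been picked from the same libraries as called genes with the largest folds, so this shows little about stability. HDSC01199CG00030 and HDSC01568CG00090 had 29 such alternatives each, and the other named genes 30 in each comparison. Leaving out 1 library at a time gave 240 to 353 genes for the eyestalk against the cephalic tentacle, 270 to 402 against the epipodial tentacle and 117 to 184 between the tentacles, and 0 for the left-right contrasts and their differences. In the following, the 3 organ comparisons are in that order, and the cause of the differences was not tested. With no filter, where 17233 genes were tested, the counts were 542, 631 and 324. DESeq2 called 568 in the eyestalk against the epipodial tentacle and 310 between the tentacles, and voom weights 627 and 333. limma called 148 genes in the eyestalk against the cephalic tentacle on log2(FPKM + 1), 137 on log2(FPKM + 0.1) and 121 without the FPKM filter, and 251 between the tentacles on log2(FPKM + 1). Fitting only the 16 libraries compared gave 177 genes in the eyestalk against the cephalic tentacle. The replicate block shared by all organs gave 412, 479 and 254 genes. With the replicate block and without the 8 doubted libraries the counts were 657, 809 and 539.

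With no filter, the left-right contrast of the cephalic tentacle had 1 call (HDSC01355CG00060), and its differences between organs had 1 for the eyestalk and cephalic tentacle and 1 for the eyestalk and epipodial tentacle (the same gene) and 2 between the tentacles (HDSC01860CG00060 and HDSC11656CG00010). These genes were singled out after their values were seen. In the epipodial tentacle, DESeq2 called 1 gene, limma on log2(FPKM + 0.1) 1 with and 1 without its filter, and the 8 libraries alone with the replicate block 1. DESeq2 called 1 gene for the difference between the tentacles. The replicate block, shared or within organ, left the left-right contrasts of all 24 libraries at 0 calls, and of the organ counts it moved that between the tentacles by over 1.5 times. Left and right libraries of 1 number had correlations of -0.13, 0.29, 0.25 and 0.61 in the eyestalk, where 6 of 8 libraries correlated best with their own number, and -0.24, 0.05, 0.13 and 0.17 in the cephalic tentacle, where 1 of 8 did. With the epipodial side read from the title letter, the correlations of left-right fold changes with the eyestalk and the cephalic tentacle turned from 0.069 and -0.163 to -0.069 and 0.163, by construction. The gene list alternatives, matching and estimated correlation, were not run, since no identifier has a name. Simulated 4-fold changes between left and right were recovered in 0% to 2% of cases in the fit of 24 libraries.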

Other observations

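The tests of identifiers, of side labels and of regrouped libraries below were set out before their results were seen, except the direction of the identifier pairs and the splits balanced over numbers, which were chosen only after.

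Genes called in the eyestalk against the epipodial tentacle often shared the part of the identifier before the letters CG. Among the 365 called genes 37 pairs shared it, where random draws of as many genes gave 14.6 pairs on average and at most 35 in 10000 draws (permutation p = 1e-04, the smallest these can give). Of the 37 pairs 31 (83.8%) went in the same direction, against 67.6% on average when directions were shuffled among the called genes (permutation p = 0.0315). If that part names a stretch of the assembly, which the sources used here do not say, neighbouring genes or copies of 1 gene may be called together, and reads shared between copies could do the same.

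The conflict in the epipodial side labels could not be settled. If the sides were swapped, left-right fold changes might run against those of the other organs, but over 7341 genes the correlation was 0.069 with the eyestalk and -0.163 with the cephalic tentacle. The exact permutation p over 16 swaps of sides within numbers was 0.125 and 0.5, and 0.125 is the smallest these can give. Genes are not independent replicates.

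Other splits of the same libraries were counted for each comparison. For the eyestalk against the cephalic tentacle 2 of 100 splits called as many genes as the real one, with 321 genes in the real split and 487 in the highest other. For the eyestalk against the epipodial tentacle 1 of 100 did, the real split itself, with 365 genes against at most 1. Between the tentacles it was 1 of 100, with 164 genes against at most 1. The numbers pair the libraries across organs, so 100 splits that keep every number equally on both sides, as the real ones do, were also drawn for each, after the other splits had been seen. Of these 1 of 100, the real split, called as many genes in the eyestalk against the epipodial tentacle (at most 0 in the others). Between the tentacles it was also 1 of 100 (at most 1), the smallest share that 100 splits can give. The splits treat each library as its own unit. If left and right libraries of 1 number come from 1 animal, they cannot exclude chance. For the eyestalk against the cephalic tentacle 4 of 100 did, with at most 1286 genes. Its share is under 5% in both draws, but some other splits called more genes than the real one. This points to a structure of the samples, so the real split stands out less here than in the other 2 comparisons. The 3 balanced splits that exceeded it, with 1286, 1107 and 913 genes, parted the 7 libraries of low detection 1 and 6, 1 and 6, and 0 and 7, against 3 and 4 in the real split. Other balanced splits that parted them 1 and 6 called only 0 or 1 genes, and a split that parted them 4 and 3 called 127. The first draw's split with 487 genes parted them 5 and 2, as uneven as 31 splits of which 28 called 0 genes.

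For the left-right contrasts the real split had 0 genes, so every split calls as many by construction and the count says nothing about chance. It was 35 of 35 in each organ, with at most 368 in the eyestalk, 26 in the cephalic tentacle and 0 in the epipodial tentacle, where the 7 other splits that part all 4 pairs also gave 0. For the average over the eyestalk and cephalic tentacle and the 3 differences between organs it was 100 of 100, with at most 1314 genes for the average and 1561, 52 and 163 for the differences of eyestalk and cephalic, cephalic and epipodial, and eyestalk and epipodial tentacle. The high counts point to a structure of the samples. The eyestalk split with 368 genes put the 3 libraries of low detection and right eyestalk replicate 2, with its dominating gene, against the other 4. The 4 other splits with the 3 libraries of low detection on 1 side called 0 genes, as did the rest. The cephalic split with 26 genes had 0 and 4 libraries of low detection, and the split with 1561 genes had 0 and 7 on the sides of its contrast. Not every high count followed low detection: the split with 52 genes had 2 and 2 such libraries, and that with 163 genes had 2 and 1.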
